A study of Danio rerio with 6 samples.

How the data were processed

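The series holds 6 libraries of whole zebrafish embryos: MeDIP-seq at 80% epiboly (2 control, 2 dnmt1 morphant) and RNA-seq at the 10-somite stage (1 control, 1 dnmt1 morphant), per the labels. Tools named in the submitters' processing notes are TopHat2, BWA, HTSeq 0.6.1 and MACS2, with no role stated for each. The genome build, peak threshold, input control and read totals of the MeDIP libraries are not given in the sources used here.

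Each RNA table gives counts of unique reads per Ensembl gene, not normalized, and RPKM, both deposited by the authors and named so per the file headers. The RPKM deposited by the authors equal the count divided by the listed gene length and by the library total in the header. Genes listed with a dash were read as 0. The 25022 rows held 24832 gene IDs, and the 376 rows that share an ID were summed. The tables hold 9.9 M (control) and 10.05 M (morphant) reads (M, megareads). Symbols came from an Ensembl ID table for 18423 IDs. Where that table gave none or only a human-style capital name, the RefSeq gene of the best protein match listed by the authors was taken (7297 IDs), which named the same gene for 93.8% of 3734 IDs that could be checked. For 4874 IDs no symbol was found.

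Each MeDIP list gives the chromosome, start, end and fold enrichment of peaks, a ratio deposited by the authors for each library on its own, per the file headers. Every list holds 65516 peaks and ends part-way through a chromosome: chromosome 19 in the controls and chromosome 21 in the morphants. Lists were therefore compared on the 10 chromosomes that all 4 cover completely (1 and 10 to 18). Positions are printed as the lists give them. The authors' fold enrichment was used to rank or filter peaks within a list, and its medians are compared between lists only in the last paragraph. Overlap meant at least 1 shared base. Merged regions were counted by the lists with a peak in them. Group means of peaks were compared by an exact two-sided permutation test. Nothing in the labels says that replicates came from separate clutches, so the spread between replicate libraries may be technical. The p-value depends only on the rank of the observed split among 6 and cannot go below 0.33. It does not measure that spread.

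RNA ratios were computed with edgeR 4.0.16 (R 4.3.3) as log2 CPM with a prior count of 2 and total-read scaling, for genes with at least 50 reads over both libraries. With 1 library per group there is no p-value and no SE. Genes are described by a size rule of 2-fold. The fold is the ratio of CPM without a prior, with a 95% exact (Clopper-Pearson) interval of the morphant share of the gene's reads. Reads are not independent molecules, so intervals cover counting error only. The median log2 ratio of each of 20 gene lists, 19 kept as fixed before the data were examined and 1 changed later (below), was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list is described as high or low at or beyond percentiles 97.5 and 2.5, as a description of these libraries. List genes were matched by symbol, and genes not found that way did not enter. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 did the rest.

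Genes named in the text follow a rule set before the data were examined. It takes dnmt1, the 10 largest ratios in each direction and up to 4 members of each list by size. It also takes all members past 2-fold of the DNA methylation and Nodal lists. Genes with only a clone or placeholder name, or no symbol, were left out of the 10 largest. For MeDIP, the 3 lost and 3 gained regions of highest mean fold enrichment are named. Genes chosen later are marked. A gene of the cell cycle arrest and apoptosis list is not reported here; it was taken out of that list, which was renamed, after the results were seen. The count, median and percentile given are those of the changed list. Alternatives were TMM scaling, a prior count of 0.5, other read minimums, RPKM with a pseudocount of 1, size rules of 1.5-fold and 4-fold, the upper part of each peak list, equal numbers of top peaks, a reciprocal overlap of 50%, leaving out each MeDIP library, and pairing by replicate number.

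The steps were tested on simulated data. With counts for 13589 genes drawn from the means and sizes of the RNA libraries, the 2-fold rule found 100% of genes changed 2.5-fold, 4-fold or 8-fold, 2% of those changed 1.5-fold and 0.06% of unchanged genes, counting error only. Of 100 unchanged lists of 15 genes 7 were called, and all 100 lists shifted 1.2-fold were called. These lists too held counting error only. Genes of the RNA libraries varied more, so these shares do not give the sensitivity of the list step in these data. Synthetic peaks gave back all 1650 regions made, with the right lists.

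Placement of peaks in genes and promoters, and RNA ratios of genes with lost or gained promoter regions, were planned but not analysed here, because no gene coordinates on the authors' build were used here.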

Results

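Whole zebrafish embryos were profiled in 6 libraries. MeDIP-seq, in which DNA fragments carrying 5-methylcytosine are pulled down with an antibody and sequenced, was done at 80% epiboly, late in gastrulation, on 2 control and 2 dnmt1 morphant libraries. RNA-seq was done at the 10-somite stage on 1 control and 1 dnmt1 morphant library. Morphants are embryos injected with a morpholino, an antisense oligonucleotide that blocks translation or splicing of its target. Whether the control embryos were injected is not given in the sources used here. The target here was dnmt1, the enzyme that copies DNA methylation onto newly made strands. The RNA libraries held 9.9 M (control) and 10.05 M (morphant) reads assigned to genes (M, megareads). For MeDIP the deposited values are peak lists, and the read depth behind them is not given in the sources used here. The comparisons asked which methylated regions and which transcripts differed between morphant and control embryos.

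Fewer regions were listed as methylated in the morphants at 80% epiboly. On the 10 chromosomes that all 4 lists cover completely, the control lists held 64400 and 65490 peaks and the morphant lists 47665 and 49396. The morphant mean was 48531 ± 1224 (SD, n = 2) against 64945 ± 771 (SD, n = 2) in controls, a ratio of 0.747. The peaks covered 93.5 ± 0.1 Mb in controls and 71.5 ± 0.3 Mb in morphants (SD, n = 2 each). Every chromosome compared showed the deficit: the ratio lay between 0.731 on chromosome 18 and 0.761 on chromosome 15. In 1 Mb windows with a mean of at least 50 control peaks, both morphant lists held fewer peaks than both control lists in 509 of 511 windows, and the ratio was below 1 in all 511. The lowest ratio, 0.493, was on chromosome 1 from 56000001 to 57000000, where the controls had 66 and 70 peaks and the morphants 33 and 34. The highest, 0.915, was on chromosome 16 from 36000001 to 37000000. The difference between groups was many times the spread between replicates, but an exact permutation test of 2 against 2 lists cannot give a two-sided p below 0.33, the value found here. Peak numbers also move with read depth and pull-down efficiency, which were not given.

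**Figure D1:**
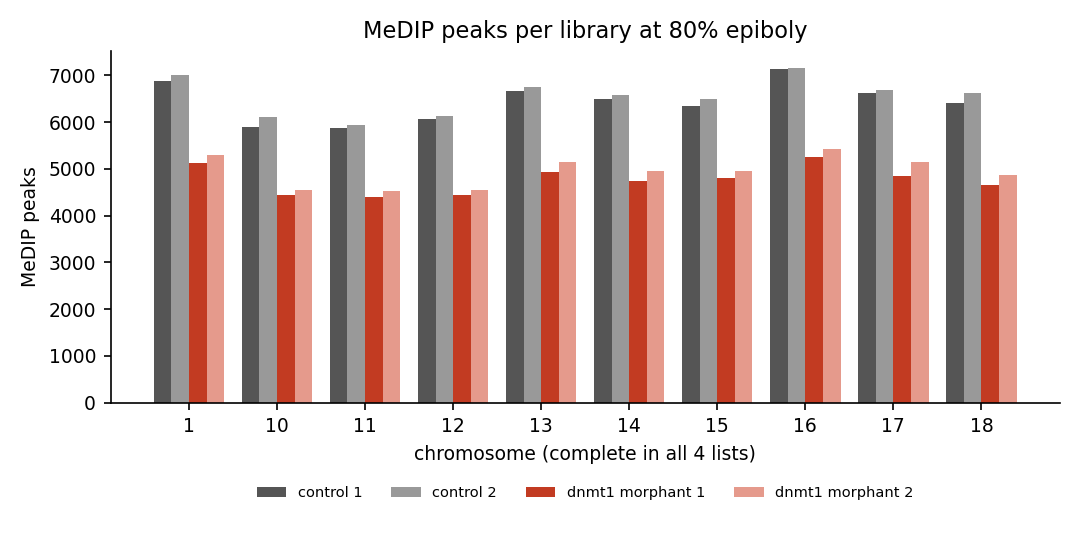
Number of MeDIP peaks on each of the 10 chromosomes that all 4 lists cover completely, with 1 bar per library (2 control, 2 dnmt1 morphant). On every chromosome both morphant bars lie below both control bars, with a morphant over control ratio of 0.731 to 0.761.

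The peak lists also differed in which regions they held. Merging overlapping peaks gave 83479 regions, of which 29017 had a peak in all 4 lists. Of the 53068 regions found in both control lists, 11314 (21.3%, 95% exact binomial interval 21.0 to 21.7) had no peak in either morphant list and are called lost. Of the 34039 regions found in both morphant lists, 2320 (6.8%, interval 6.6 to 7.1) had no peak in either control list and are called gained. These intervals cover only the number of regions, taken as independent, and no variation between libraries. The other ways of splitting the 4 lists into pairs gave 1177 to 1412 regions exclusive to a pair. Each of those pairs joins 1 control and 1 morphant list, so only the control-morphant split sets longer lists against shorter ones. Longer control lists alone would raise the number of lost regions, so the splits do not show a difference beyond list length. The bases covered by the control replicates overlapped with a Jaccard index of 66.4%, those of the morphant replicates with 51.7%, and control and morphant lists with 47.7 to 48.2%. The strongest lost regions, by the authors' fold enrichment per peak, lay on chromosome 1 from 20856027 to 20857530 (14.4 and 16.7 in the controls), on chromosome 14 from 7722367 to 7723600 (12.3 and 13.7), and on chromosome 13 from 23395641 to 23396698 (11.5 and 14.1). The strongest gained regions lay on chromosome 16 from 26006039 to 26007607 (9.72 and 8.9 in the morphants), on chromosome 17 from 45218553 to 45219812 (8.31 and 9.22), and on chromosome 16 from 26066866 to 26068487 (11.5 and 4.93). The genome build is not given in the sources used here, and the genes at these positions were not analysed here.

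Control peaks missing from both morphant lists were not only the weakest ones. Among control 1 peaks, ranked by fold enrichment and cut into 4 equal groups, 37.4% of the lowest group had no peak in either morphant list, against 12.2% of the top group, and 98.4% of that top group had a peak in the other control list. For control 2 these shares were 38.4%, 12.5% and 98.1%. The excess of lost over gained regions depended on list length: with the 47665 strongest peaks taken from every list, 6795 regions were lost and 5994 gained, where a control peak below the cut counts as absent. Leaving out any 1 list relaxes the definition and gave 17214 to 18306 lost and 3646 to 6938 gained regions.

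**Figure D2:**
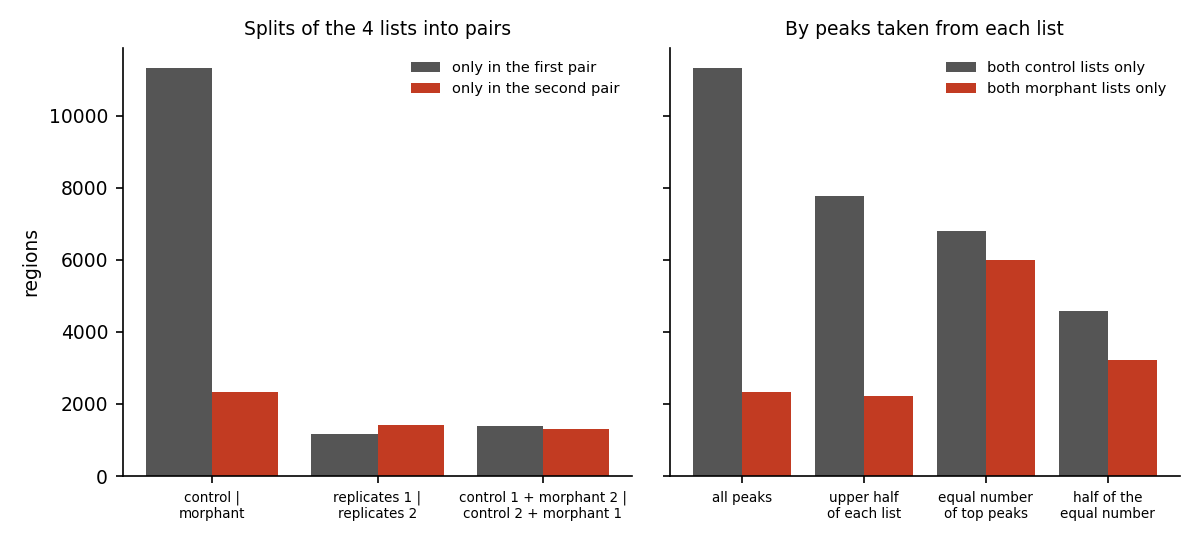
Left, merged MeDIP regions with a peak in both lists of 1 pair and in neither list of the other pair, for the 3 splits of the 4 lists into pairs. Right, regions found only in both control lists (grey) or only in both morphant lists (red) by the peaks taken from each list; 11314 and 2320 regions with all peaks become 6795 and 5994 with an equal number of top peaks.

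In the RNA libraries the targeted transcript, dnmt1 (ENSDARG00000030756), had 2423 reads in the control and 3194 in the morphant library, a ratio of 1.3 (95% exact counting interval 1.23 to 1.37). A morpholino that blocks translation leaves its target RNA in place, and which kind was used is not given in the sources used here, so the dnmt1 level does not check the knockdown. There was 1 library per group, so no difference in RNA has a replicate check, and all intervals on ratios cover counting error only.

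Of 13575 genes with at least 50 reads over both libraries, 220 were at least 2-fold higher and 74 at least 2-fold lower in the morphant library. At 4-fold the numbers were 43 and 2, and 20 genes were at least 8-fold higher. Splitting each gene's reads at random between the libraries, in 100 draws, gave a mean of 4 higher and 3.7 lower genes. Genes with only a clone or placeholder name, or no symbol, were left out of the ranking that follows. The 10 largest ratios upward among the others belonged to rspo1, rbl2, atxn1b, gadd45aa, isg15, casp8, bbc3, phlda3, MAP3K20 and foxo3b. The Wnt agonist gene rspo1 went from 3 to 163 reads, a ratio of 53.5 (interval 18 to 262). The retinoblastoma-family gene rbl2 had 66 and 1634 reads (24.4-fold, 19.1 to 31.7), the ataxin gene atxn1b 38 and 919 (23.8-fold, 17.2 to 33.9), and the stress kinase gene MAP3K20 17 and 247 (14.3-fold, 8.75 to 25.0). The 10 largest ratios downward among the ranked genes belonged to sult2st3, cacng2a, COQ8A, aga, mrpl4, lrrtm1, mettl25b, btk, dnai1.2 and duox. The sulfotransferase gene sult2st3, which has close relatives that could share its reads, had 52 reads in the control and 7 in the morphant library (0.133-fold, interval 0.0508 to 0.293). The calcium channel subunit gene cacng2a had 87 and 17 (0.192-fold, 0.107 to 0.326). The mitochondrial ribosomal protein gene mrpl4 had 317 and 112 (0.348-fold, 0.278 to 0.433), and the NADPH oxidase gene duox 382 and 148 (0.381-fold, 0.313 to 0.462). The counts depended on the read minimum: with at least 200 reads, 86 genes were higher and 22 lower, and with no minimum 1076 and 923.

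A short list of genes linked to cell cycle arrest and apoptosis stood high in the morphant library. Of its 13 members with enough reads, 11 were at least 2-fold higher, none was 2-fold lower, and the median log2 ratio was 2.69, at percentile 100 of 10000 random lists matched on expression (middle 95% of those medians, -0.14 to 0.16). The DNA damage gene gadd45aa had 6 and 164 reads (26.9-fold, 12.1 to 74.4), the apoptotic caspase gene casp8 35 and 615 (17.3-fold, 12.3 to 25.1), the cell death gene bbc3 (puma) 28 and 455 (16.0-fold, 10.9 to 24.4), and phlda3 66 and 972 (14.5-fold, 11.3 to 18.9). The transcription factor gene foxo3b, also on this list, had 338 and 4393 reads (12.8-fold, 11.4 to 14.3). Further members, named after their values were seen, were the ubiquitin ligase gene mdm2 (754 and 4627 reads, 6.04-fold), the cell cycle inhibitor cdkn1a (85 and 569, 6.59-fold) and cyclin G1, ccng1 (4465 and 17898, 3.95-fold). The members within 2-fold, also named after their values were seen, were aifm2 (1.23-fold) and btg2 (1.04-fold). Members below the read minimum, named in the same way, were pmaip1 (5 and 2 reads), fas (5 and 4) and zmat3 (0 and 3). A member with few control reads could pass the minimum only by being higher in the morphant library, as gadd45aa was. Broader terms were mixed and their medians were far smaller. In the authors' gene ontology annotation, looked up after the results were seen, cell cycle arrest had a median of 0.03 over 40 genes (percentile 59.2, 3 at least 2-fold higher) and apoptosis 0.06 over 131 (percentile 89, 3 higher and 1 lower), neither called. Positive regulation of apoptosis (0.15 over 44, 31 above 0, percentile 99.35) and cell death (0.25 over 29, 24 above 0, percentile 99.92) were high. Checkpoint and DNA damage terms went the other way. Cell cycle checkpoint (-0.15 over 23, 5 above 0, percentile 0.4) and DNA repair (-0.07 over 108, 38 above 0, percentile 0.1) were low. So were response to DNA damage stimulus (-0.08 over 36, percentile 2.16) and response to ionizing radiation (-0.10 over 26, percentile 1.69).

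**Figure D3:**
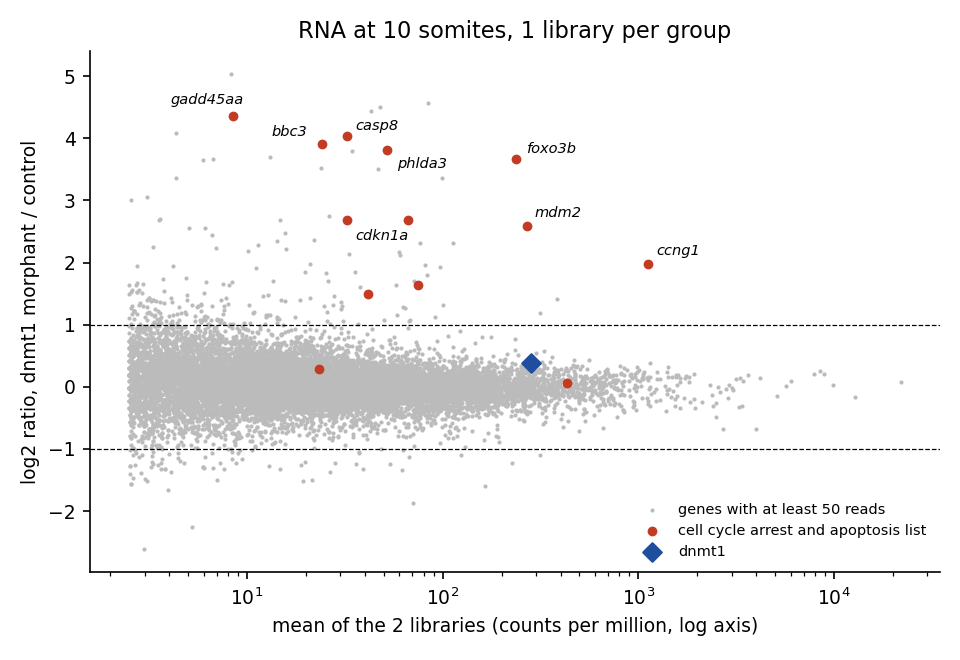
Log2 ratio of the dnmt1 morphant over the control RNA library against the mean of both in CPM (counts scaled to the library total, log axis), with 1 point per gene of at least 50 reads; red points are the cell cycle arrest and apoptosis list, the blue diamond is dnmt1, and dashed lines mark 2-fold. Of the 13 members of that list, 11 lie above the upper line.

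The neural and BMP lists lay low, with no member 2-fold changed, while broader annotation terms, given at the end of this paragraph, were mixed. In the list of neural plate and neuronal genes, 13 of 16 members were below 0 and the median log2 ratio was -0.31 (percentile 0, random medians -0.13 to 0.14). The midbrain-hindbrain gene en2a had a ratio of 0.584 (interval 0.474 to 0.717), the proneural gene ascl1a 0.584 (0.373 to 0.902), the neural progenitor gene sox2 0.675 (0.612 to 0.746) and the eye and spinal cord gene pax6b 0.680 (0.587 to 0.786). In the BMP list, 12 of 14 members were below 0 and the median was -0.35 (percentile 0, random medians -0.14 to 0.17). The BMP antagonist gene chrd had a ratio of 0.564 (0.515 to 0.617), the chordin-cleaving protease gene tll1 0.652 (0.565 to 0.752), the BMP target id1 0.676 (0.643 to 0.710) and the ligand gene bmp4 0.739 (0.614 to 0.889). Among the authors' gene ontology terms, looked up after the results were seen, neurogenesis was low (median -0.14 over 18 genes, percentile 1), nervous system development was not called (0.07 over 114, percentile 90.5) and central nervous system development was high (0.23 over 42, percentile 99.98, 31 above 0). Further neural terms were low: regulation of neurogenesis (-0.25 over 10, percentile 0.27), midbrain-hindbrain boundary development (-0.20 over 11, percentile 1.27) and hindbrain development (-0.13 over 20, percentile 1.71). Forebrain development was not called (-0.04 over 39, percentile 10.7). Negative regulation of BMP signaling was low (-0.23 over 13, percentile 0.24), and the BMP signaling pathway term was not called (0.08 over 14, percentile 78). Anterior/posterior pattern formation was low too (-0.10 over 41, percentile 0.38). So was negative regulation of transcription from RNA polymerase II promoter (-0.10 over 188, percentile 0). Positive regulation of transcription from that promoter was not called (0.0 over 212, percentile 18.5). Low medians were thus not limited to neural and BMP genes.

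The somite list (median -0.13, percentile 3.63) and the Kupffer vesicle and cilia list (median -0.11, percentile 3.77) lay just inside the central range. The segmentation clock genes her7 and her1 had ratios of 0.610 (0.517 to 0.718) and 0.732 (0.650 to 0.823), the presomitic gene msgn1 0.716 (0.658 to 0.779) and the myogenic factor gene myf5 0.758 (0.667 to 0.862). With at least 200 reads the somite list had a median of -0.20 at percentile 0.38, and no other setting called it. Among cilia genes, the axonemal dynein gene DNAH11 was 2.56-fold higher (1.87 to 3.53), foxj1b had a ratio of 1.52 (1.23 to 1.88), dnah5 0.678 (0.415 to 1.1) and noto 0.744 (0.565 to 0.978).

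The epidermis list and the hatching gland list lay high, again with every member within 2-fold. The epidermis and enveloping layer list had a median of 0.18 (percentile 99.7, 10 of 15 members above 0), with the claudin gene cldni at a ratio of 1.37 (1.24 to 1.51), foxi3a at 1.34 (0.989 to 1.82), the keratin gene krt92 at 1.24 (1.21 to 1.28), and E-cadherin, cdh1, in the other direction at 0.681 (0.644 to 0.720). The hatching gland, yolk syncytial layer and pronephros list had a median of 0.15 (percentile 97.7, and 97.4 with at least 200 reads, which is inside the central range), with 10 of 14 members above 0 and no tissue tested on its own. In it the kidney cadherin gene cdh17 had a ratio of 1.91 (1.52 to 2.41), the hatching gland genes ctslb and he1.1 had 1.76 (1.46 to 2.11) and 1.52 (1.40 to 1.65), and the kidney field gene lhx1a had 0.595 (0.485 to 0.729). The interferon list, with 6 members read deeply enough, had a median of 0.48 (percentile 98.6) and all 6 above 0. Its ubiquitin-like gene isg15 had 3 and 84 reads (27.6-fold, interval 9.12 to 136), the kinase gene eif2ak2 16 and 34 (2.09-fold, 1.12 to 4.06), trim25 56 and 86 (1.51-fold, 1.07 to 2.16) and irf1b 140 and 187 (1.32-fold, 1.05 to 1.65). With no read minimum the interferon median was 0.25 at percentile 81.5.

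**Figure D4:**
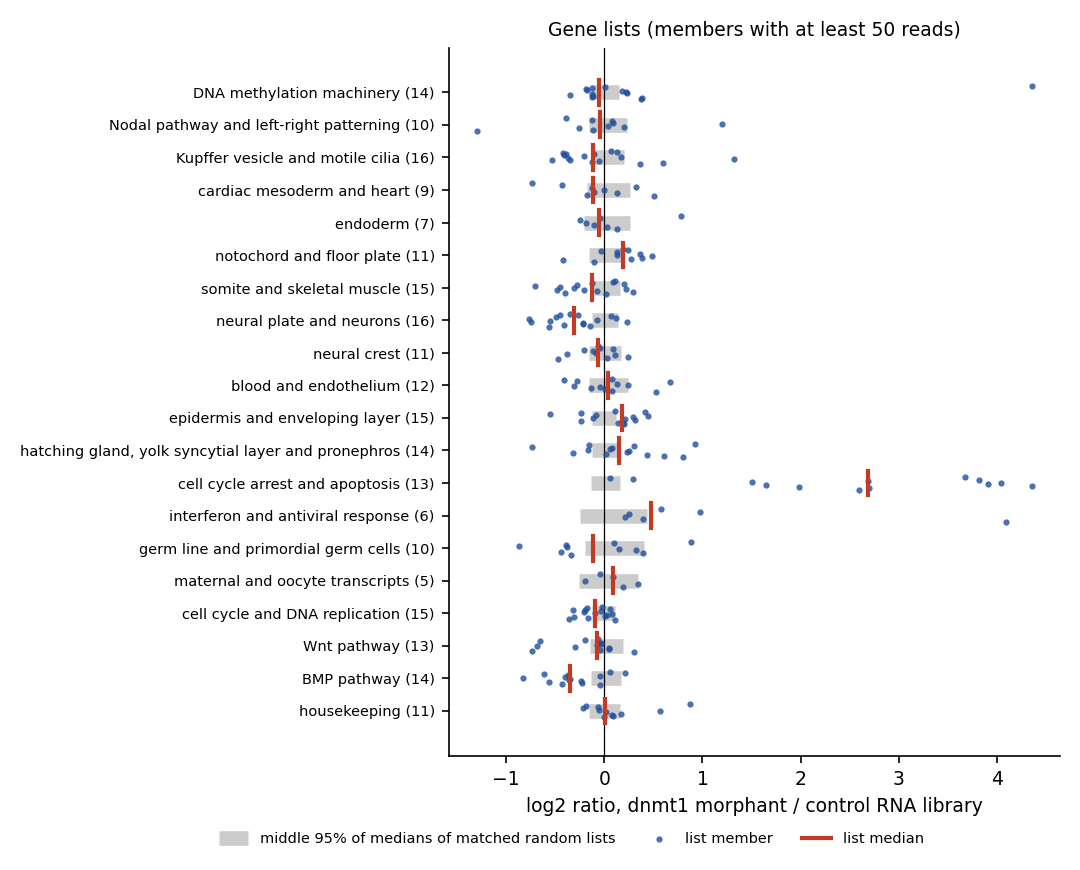
Log2 ratio (dnmt1 morphant over control RNA library) of the members of the 20 gene lists with at least 50 reads (blue points, number in brackets), with the list median (red) and the middle 95% of medians of matched random lists (grey). The cell cycle arrest and apoptosis median stands at 2.69, the neural and BMP medians at -0.31 and -0.35.

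Among genes of DNA methylation and its removal, gadd45aa was the only one of 14 past 2-fold, and the list median was -0.05 (percentile 20.5). The de novo methyltransferase genes dnmt3ab and dnmt3bb.2 had ratios of 1.32 (0.929 to 1.88) and 0.786 (0.748 to 0.825). With no read minimum this list had a median of 0.19 at percentile 98.4. In the Nodal and left-right list (10 members, median -0.04, percentile 21.7), the Nodal inhibitor gene lft1 was at least 2-fold lower, with 85 and 34 reads (0.394-fold, 0.257 to 0.593), and the Nodal co-ligand gene gdf3 was at least 2-fold higher, with 152 and 358 reads (2.32-fold, 1.91 to 2.82). The other named members were elovl6 at a ratio of 0.754 (0.509 to 1.11) and dand5 at 0.834 (0.633 to 1.1). Members below the read minimum were named after their values were seen. The left-sided Nodal ligand spaw had 3 reads in each library, too few to show a difference. In the control and morphant libraries ndr2 had 11 and 3 reads, lft2 6 and 3, gsc 28 and 18 and mixl1 8 and 9.

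For the remaining lists the median lay inside the range of matched random lists and every member was within 2-fold. Notochord and floor plate genes had a median of 0.19 (percentile 96.6). Of these, col8a1a had a ratio of 1.40 (1.29 to 1.52) and noto, in the other direction, 0.744 (0.565 to 0.978). The ratio was 1.32 (0.798 to 2.22) for ihhb and 1.29 (1.07 to 1.55) for foxj1a. Of the 15 genes on that list 13 were found by symbol, and col2a1a was not. A gene named COL2A1, looked up after the results were seen (1716 and 2962 reads, 1.70-fold), did not enter the median. The percentile is near the threshold, so the call could change with it. Cardiac genes had a median of -0.11 (percentile 9.19), with the heart matrix gene has2 at 0.599 (0.522 to 0.685) and nkx2.5 at 1.46 (0.833 to 2.59). Endoderm genes had a median of -0.05 (percentile 28.0), with nkx2.3 at 1.75 (1.18 to 2.64). Neural crest genes had a median of -0.06 (percentile 24.2), with tfap2a at 0.771 (0.729 to 0.816). Blood and endothelial genes had a median of 0.04 (percentile 54.8). The globin gene hbae3 had a ratio of 1.62 (1.06 to 2.51) and gata1a 1.45 (1.16 to 1.82). Among lower members were lcp1 at 0.753 (0.651 to 0.870) and klf17 at 0.804 (0.731 to 0.885). Wnt pathway genes had a median of -0.07 (percentile 15.8), with wnt5b at 0.598 (0.547 to 0.652) and sp5a at 0.619 (0.543 to 0.705). Germ line genes had a median of -0.12 (percentile 7.35), with tdrd7a at 0.536 (0.361 to 0.787) and mov10l1 at 1.90 (1.21 to 3.06). In RPKM their median was -0.17 at percentile 2.07, and no other setting called this list. Cell cycle genes had a median of -0.09 (percentile 9.79), with the replication licensing gene mcm2 at 0.779 (0.748 to 0.811). Maternal transcripts had a median of 0.09 (percentile 66.5, 5 members), with npm2b at 1.27 (0.95 to 1.70). Housekeeping genes had a median of 0.01 (percentile 60.3), with b2m at 1.88 (1.22 to 2.96).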

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

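Choices planned before the data were examined were each changed in turn, and no called list, gene count or named gene past 2-fold changed direction. Of 97 alternative values for the 20 gene list medians, 92 stayed on their side of the percentile thresholds. With no read minimum the DNA methylation list moved from -0.05 to 0.19 (called high) and the interferon list to 0.25 (no longer called). With at least 200 reads the somite list was called low at -0.20 and the hatching gland list was no longer called at 0.15. In RPKM the germ line list was called low at -0.17. The causes were not tested. The numbers of genes higher and lower (220 and 74) became 1076 and 923 with no read minimum, 86 and 22 with at least 200 reads, 43 and 2 at 4-fold, and 830 and 440 at 1.5-fold, since these settings change how many genes can pass. With TMM they were 197 and 91, with a prior count of 0.5 239 and 89, and in RPKM 160 and 62, of which 107 and 32 were among the genes of the main count. Of 427 alternative log2 ratios of named genes, 416 stayed within their counting interval and 11 moved, all in RPKM, where the pseudocount pulls low genes toward 0.

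The ratio of MeDIP peaks (0.747) was 0.734 to 0.761 without any 1 library. Taking the upper part of each list holds the ratio near its main value by construction (0.749), and equal numbers of peaks fix it at 1, so neither tests it. The gap in Jaccard index between replicate pairs and control-morphant pairs (11.09 points) was 12.18 in the upper part of each list, 12.14 with equal numbers and 11.37 with 50% of that number, and the gap in shared peaks (7.68 points) was 9.03 with the reciprocal overlap. Lost regions (11314) became 6795 with equal numbers and 4591 with 50% of that number, and gained regions (2320) became 5994 and 3206. The cuts leave fewer peaks per list, and a region counts as gained when its control peaks lie below the cut. In the upper part of each list there were 7769 lost and 2226 gained regions, and with the reciprocal overlap 12382 and 2801. Leaving out 1 library gave 17214 to 18306 lost and 3646 to 6938 gained regions, as fewer lists must agree. Within replicate numbers (a replicate block), the peak ratio was 0.747 and the means were 25746 lost and 9645 gained regions, where a single list per group defines them. Deviations of same-numbered replicates correlated at -0.08 over windows, so the numbers were not taken as pairs. MeDIP placement and promoter comparisons were not run. With 1 RNA library per group, pool-to-pool variation has no measure, and unknown MeDIP depth limits every count of peaks.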

Other observations

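All tests in this part were chosen after the results were seen. The authors' gene ontology annotation gave 752 process terms with 10 to 300 genes of at least 50 reads. Of their median log2 ratios 67 lay at or above the upper and 40 at or below the lower percentile threshold of matched random lists, where 18.8 on each side would arise by chance among independent terms. Collagen fibril organization stood at a median of 0.45 over 22 genes (16 above 0, percentile 100). In it COL14A1 had 154 control and 395 morphant reads (2.52-fold, interval 2.09 to 3.06) and col1a2 89 and 196 (2.17-fold, 1.68 to 2.82). The collagen cross-linking gene loxl2b had 16 and 43 (2.65-fold, 1.46 to 5.03) and the collagen gene COL2A1 1716 and 2962 (1.70-fold, 1.60 to 1.80). The collagen chaperone gene serpinh1a had 2617 and 3965 (1.49-fold, 1.42 to 1.57). COPI coating of Golgi vesicles, a step of secretory traffic, had 10 of 11 genes above 0 (median 0.29, percentile 99.99), with copz1 at 1.3-fold (1.16 to 1.46) and copb1 at 1.24-fold (1.18 to 1.3).

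At the other end, dorsal/ventral pattern formation had 29 of 42 genes below 0 (median -0.20, percentile 0). Besides lft1, irx4b had 50 and 20 reads (0.394-fold, 0.222 to 0.673) and zeb2b 123 and 61 (0.488-fold, 0.353 to 0.669), while tob1a was higher with 1144 and 2018 reads (1.74-fold, 1.61 to 1.87). Digestive tract morphogenesis had a median of -0.27 over 17 genes (percentile 0.01) and DNA strand elongation in replication -0.19 over 15 genes (percentile 0.3).

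The cell cycle arrest and apoptosis list stood far above matched lists. Library scaling or a few abundant genes do not account for it, since they would move random lists matched on expression as much, and the medians of those reached only 0.16 at the upper end of their middle 95%, against 2.69 for the list. Counting error does not either, since 12 members had intervals above 1. Injection or the morpholino itself could raise these genes, as could loss of dnmt1. These cannot be told apart, because no injected control is named, and more libraries of this design would not separate them. There is also 1 library per group, and dnmt1 RNA at 1.3-fold does not measure the protein. A pool of embryos that differed for other reasons is open too.

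The lower neural list may reflect the age of the embryos sampled. A younger morphant pool would hold more presomitic and clock RNA, which fades as somites form. The median of those genes was -0.29 over 15 genes (percentile 0.01). However, her7, her1, msgn1 and others of them are in the somite list above, so their low values were known beforehand. Fewer presomitic cells would also lower them at any age, so a younger pool is not excluded. An older pool stays open too. Of 27 listed muscle differentiation genes, which increase with age, 11 had enough reads, 9 of them above 0 and 2 below. Their median of 0.10 (percentile 85.1) lay inside the random range, so it does not decide the question. Loss of neural or progenitor cells was not tested.

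Fewer peaks in the morphant MeDIP lists could come from less methylation, or from lower read depth or weaker pull-down. The last 2 cannot be excluded, because peaks were fewer in all 511 windows compared (median ratio 0.748, 0.493 to 0.915) and no read totals were at hand. The authors' fold enrichment was lower too. In regions with a peak in all 4 lists its median was 6.34 and 6.36 in the control lists and 4.93 and 4.96 in the morphant lists. This does not separate less methylation from weaker pull-down. A loss of weak peaks that keeps their order, apart from noise independent between libraries, was tested with every list cut to its 23832 strongest peaks. Under it a control and a morphant list share at least as many peaks as the less similar replicates do. The control replicates shared 74.2%, the morphant replicates 54.1% and control-morphant pairs 51.4 to 51.8%, which is 2.32 points below the morphant replicates at the nearest. The control share does not enter the test, because less noise in the control lists would raise it. With 1 morphant pair the gap has no spread to judge it by, so such a loss cannot be excluded. A change of background with weaker pull-down, or another cause shared by the morphant libraries, which could reorder peaks, is open too, beside a change in methylation.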
